A study of Homo sapiens with 4 samples.

How the data were processed

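BEAS-2B cells, an immortalised line of human bronchial epithelial cells, were transfected with a METTL16-overexpressing plasmid or with an empty plasmid as control, per the labels. For each of the 2 arms, 1 input library and 1 library after immunoprecipitation with an m6A antibody were sequenced (MeRIP-seq), which gives 4 libraries in 4 groups of 1. Per the labels' protocols, ribosomal RNA was depleted, the RNA was fragmented, and a strand-marking dUTP protocol with paired-end sequencing was used. Reads were trimmed with fastp 0.19.4 and the build was hg38, per the submitters' processing notes. The aligner, the peak caller, the program behind the expression levels, the annotation version and the use of strand when reads were counted are not given in the sources used here.

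The values came from 1 table of the authors' own comparison of the overexpression arm with the control arm. It holds 9466 peaks on 6763 genes, with 1 line per peak. For each peak, the authors deposited a log2 fold change of m6A, in which a value above 0 is higher in the overexpression arm. They also deposited a p-value and an adjusted p-value per peak, and every p-value in the table lies below 0.05. Peaks without that support are therefore outside all shares given here. The adjusted p-value is empty for 895 peaks, all of them at 2-fold or more. The mark of a differential peak in the authors' deposited table equals a p-value below 0.05 with an absolute log2 fold change of at least 1 in 100% of lines, and such peaks are called differential here. Input expression was deposited as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene for both input libraries, for 6546 genes, and 217 genes had none. The authors' expression fold change is the ratio of those FPKM values where both are above 0, and their log2 fold change, p-value and q-value of expression stand beside it. Where an FPKM is 0 the log2 fold change is still finite, for example 15.4 for HNRNPUL2-BSCL2, so a small value stood in for 0. Those p-values compare the reads of single libraries, not conditions. The peak length in bases, the remaining deposited value, counts from the first to the last genomic base with introns included, per the file headers and the values. The median length was 805 bases and the longest was 382029 bases, so the span of a long peak is not a methylated stretch.

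The sequencing depth of the 4 libraries is unknown, since FPKM values were used without counts, and no interval that needs depth is given. Levels in the immunoprecipitated libraries were not analysed here. Coordinates are those of the table, 1-based on hg38. Region names of peaks are the authors' labels, and a peak labelled 3'UTR need not lie at the 3' end of its gene. The spans of MAT2A and GGCX were taken from the RefSeq annotation of the same assembly. Gene symbols are the table's own, and 312 genes carried an Ensembl identifier in place of a symbol.

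From these values, peaks were counted by direction, by annotated region and by gene. Shares have exact Clopper-Pearson 95% intervals and medians have binomial order-statistic 95% intervals. Both cover the counting of peaks only, and peaks are not replicates. Input changes were computed as log2((FPKM + 1)/(FPKM + 1)) for genes with an FPKM of at least 1 in either input, with 1 value per gene, which understates the change of low genes. With 1 library per group no test between conditions was possible. No difference below has a replicate check.

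For 30 gene lists fixed before the data were examined, the members' median was placed among 10000 random lists of the same size, matched on mean FPKM in 10 equal bins. A percentile below 2.5 or above 97.5 is described as outside the range of random lists. For m6A, the peak with the smallest p-value stood for each gene. This step was tested on simulated data: when a shift of 0.1 or 0.2 (log2) was added to the input change of lists of 15 genes drawn from 5467 genes, 70.0% and 97.5% of 40 such lists passed the upper limit, and 0% passed it without a shift. The simulation used 1000 random lists and the input change only, so the m6A percentiles were not tested in this way. Its changes were independent normal values of the same spread for every gene. The 0% therefore need not hold for lists whose members move together.

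Genes were named by a rule also fixed before the data were examined. MAT2A and METTL16 were always to be named. The rule then took the 10 genes with the highest and the 10 with the lowest log2 fold change of a differential peak, at an FPKM of at least 1 in both inputs and with 1 peak per gene. It took 10 genes per direction of input change, up to 4 members per list by input change and up to 4 by differential peak, and up to 3 genes per class of m6A against expression. Genes without a symbol were left out by the rule, and genes were left out from the bottom of each ranking for room. The values of 4 genes that the rule took are not reported here. Further genes are marked in the text as chosen after their values were seen.

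Alternatives covered the p-value and fold thresholds, counting by gene, expression filters, pseudocounts, centring on the median, rescaling and the matching of random lists. The list of 40 duplicated gene families used in the closing part was written by hand after the top genes had been seen, and 2 of its name patterns were narrowed after a first run because they took in unrelated genes. A planned median of the fold enrichment over input per arm was not computed, since levels of the immunoprecipitated libraries were not analysed here. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.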

Results

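METTL16 is an RNA methyltransferase that places N6-methyladenosine (m6A) on the U6 small nuclear RNA and on hairpins in the 3'UTR of MAT2A mRNA. MAT2A encodes the enzyme that makes S-adenosylmethionine, the methyl donor of these reactions. MeRIP-seq compares RNA fragments bound by an m6A antibody with the input RNA of the same cells. The comparison asked which m6A peaks and which input transcripts differed between BEAS-2B bronchial epithelial cells with the METTL16 plasmid and those with an empty plasmid. There were 4 libraries, 1 input and 1 immunoprecipitate per arm, without replicates, and their depth is unknown. The table held 9466 peaks on 6763 genes, of which 4835 genes had 1 listed peak and 1928 had 2 or more. The 2 input libraries ranked the 6546 genes with a level almost alike (Spearman 0.994 across genes). METTL16 itself had 0 lines in the table, so its level in either arm was not analysed here, and the overexpression named by the labels could not be checked from it.

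MAT2A had a higher m6A value in the overexpression arm at the 3' end of its transcript, while its input level was nearly equal in both arms. The MAT2A peak in the 3'UTR (chromosome 2, 85544446 to 85545281) had a log2 fold change of 0.67 in the authors' deposited table, with p = 4.57e-66, the rank of 11 among all listed peaks by p. At 1.59-fold it stayed under the 2-fold threshold, and after centring on the median of all peaks it reached 1.05 on the log2 scale. Centred instead on the median of -0.18 among the most expressed of 10 equal groups of peaks, where MAT2A lay, it stayed under 2-fold. Other abundant transcripts, chosen after their values were seen, had peaks of similar value, such as EEF1A1 at 0.66 and HSP90AA1 at 0.68. Of the 25 peaks with a symbol and the smallest p, 18 were higher and 7 lower, so the value is not particular to MAT2A. A second MAT2A peak, at the stop codon (85543671 to 85544121), had a log2 fold change of 0.19 in the authors' deposited table. Input FPKM of MAT2A was 95.1 in the overexpression arm and 96.8 in the control arm. On the opposite strand, the authors' deposited table placed a peak of GGCX, which encodes the vitamin K-dependent carboxylase, at 85544719 to 85545269 with a log2 fold change of 0.74. The input level of GGCX was 4.43 and 4.09 FPKM, far below that of MAT2A. GGCX was chosen after its values were seen, and a second GGCX peak, in an intron at 85556511 to 85557086, had a log2 fold change of 1.26 in the authors' deposited table.

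**Figure D1:**
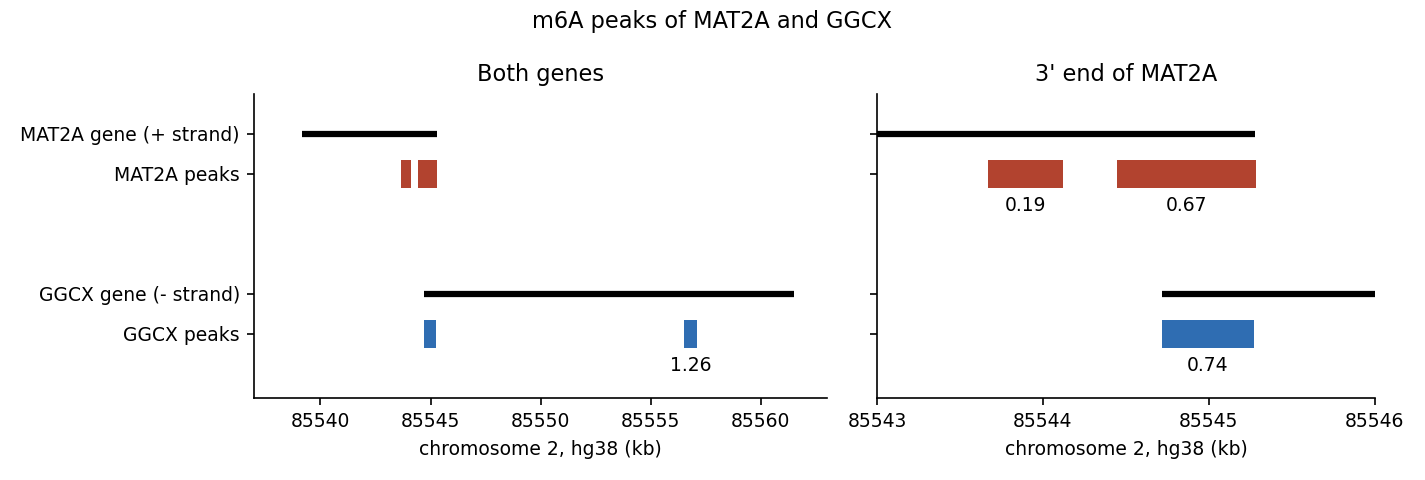
m6A peaks of MAT2A and GGCX on chromosome 2 (horizontal axis in kb, hg38), over both genes on the left and at the 3' end of MAT2A on the right. Black lines are the annotated gene spans, coloured boxes are the listed peaks, and the numbers are their log2 fold changes, overexpression over control: the 0.74 peak of GGCX lies within the bases of the longer 0.67 peak of MAT2A, on the opposite strand.

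More peaks had a lower than a higher m6A value in the overexpression arm. Of the 4132 differential peaks, 1558 were higher and 2574 were lower, a lower share of 62.3% (60.8 to 63.8). They lay on 3416 genes, of which 1415 held a higher peak, 2259 a lower peak and 258 both. Median log2 fold changes of the higher and the lower peaks were of similar size, at 1.95 and -1.94. Among the 5334 listed peaks under 2-fold, 78.7% (77.5 to 79.8) were lower. Over all listed peaks the median was -0.38 (-0.40 to -0.37), which is 1.30-fold lower. When the log2 fold changes were centred on that median, 2037 peaks were higher and 1970 lower (49.2% lower). Centring removes the common shift by construction. The median covers only peaks with a p-value below 0.05, so it is no estimate of the scaling between libraries. Values between -0.38 and 0 change sign with the centring, and the direction of any peak in that range depends on the scaling between libraries. At an adjusted p below 0.05, 742 of the differential peaks remained.

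The highest m6A values, those of SMG1P5, STAG3L1, NOMO3 and GTF2H2, were on genes with near-identical copies in the genome. SMG1P5 (chromosome 16, 30268506 to 30273165), a pseudogene of the kinase SMG1, had the highest log2 fold change among the named genes in the authors' deposited table, 12.29. STAG3L1 followed with 11.52, NOMO3 with 9.21, GTF2H2, a subunit of the transcription factor TFIIH, with 8.19, DDT with 8.10 and SMN1, the survival motor neuron gene, with 6.75, all from the authors' deposited table. Among lower peaks of the authors' deposited table, NBPF10 stood at -7.50 and GOLGA2P7 at -7.43. Reads of such genes can be assigned to any of several copies, so these values are uncertain. Of the 20 genes named by m6A, 8 belonged to such families. Genes without listed copies included RAD51D, a recombination repair gene, with 8.13 at its 3'UTR (chromosome 17, 35094995 to 35095095), and the plasmalogen enzyme gene PEDS1 with 6.98 in the authors' deposited table. ABI2 and HDGFL3 had 3'UTR peaks at 6.73 and 6.62 in the same comparison of the authors' deposited table.

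On the lower side, the mismatch repair gene MLH3 had a 3'UTR peak (chromosome 14, 75014643 to 75014868) at a log2 fold change of -8.87 in the authors' deposited table. The sorting nexin gene SNX19 stood at -7.89, the sphingosine-1-phosphate receptor gene S1PR3 at -7.33 in its 5'UTR, and the ubiquitin ligase genes UBE4B and ITCH at -7.09 and -6.55 in the authors' deposited table. KEAP1, the adaptor that marks NRF2 for degradation, had an intronic peak (chromosome 19, 10490768 to 10490968) at -6.77 in the authors' deposited table. TTC9C and DENND1A had 3'UTR peaks at -6.90 and -6.72 in the authors' deposited table. Of the 20 genes, 4 also had a differential peak the other way in the authors' deposited table: STAG3L1 at -6.37, HDGFL3 at -2.59, S1PR3 at 2.63 and DENND1A at 2.73. Input FPKM of the 8 lower genes without listed copies was within 1.5-fold between the arms, for example 8.04 and 8.47 for KEAP1. Of the 20 named genes, 11 had no adjusted p in the authors' deposited table, and all 11 were genes without listed copies. Among the named genes without listed copies, only TTC9C had an adjusted p.

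The few peaks with the smallest p were mostly higher, and most lay on abundant transcripts such as EEF1A1 and VIM. Among the 25 peaks with a symbol and the smallest p, chosen after their values were seen, 18 were higher and 7 lower, and 7 were differential. Over all 2419 peaks at an adjusted p below 0.05 the balance was the opposite, with 594 higher and 1825 lower. The translation elongation factor EEF1A1 had the smallest p in the authors' deposited table, 3.39e-222, with a log2 fold change of 0.66 at an exonic peak. VIM, which encodes the intermediate filament vimentin, had a 3'UTR peak at 0.54 and an exonic one at 0.82 in the authors' deposited table. GNAS, the stimulatory G protein alpha subunit gene, had 3'UTR peaks at 1.51, 1.52 and 0.12 but a 5'UTR peak at -1.33 in the authors' deposited table. The glycolytic enzyme gene PKM had 1.20 at a peak labelled 3'UTR, and the proteasome subunit gene PSMD2 had 1.43 at an exonic peak of the authors' deposited table. Also higher there, in the authors' deposited table, were ANXA2 at 0.92, HSP90AA1 at 0.68, TPX2 at 0.86 and LMNA at 0.86, although a start codon peak of HSP90AA1 stood at -2.37. Of the 7 lower peaks, those of 7SK at -0.31, LGALS3BP at -0.26, IFI6 at -0.24, SLC7A5 at -0.32 and PLEC at -0.30 in the authors' deposited table turn positive when centred on the median of all peaks. Centred instead on the -0.18 of the most expressed of 10 equal groups of peaks, where they lay, LGALS3BP, IFI6, SLC7A5 and PLEC stay negative. NPIPA7 at -4.53, which has near-identical copies, and an intronic peak of SLC35F1 at -3.46 in the authors' deposited table stay negative. Input levels of 7SK, BEST1 and SLC35F1 were under 0.2 FPKM in both arms. The BEST1 peak, at 0.92, lay within the bases of the FTH1 peak, at 0.61, on the opposite strand. Both are counted among the 18 higher peaks and may share reads, which was not tested for this pair. FTH1 had 166.7 against 163.3 FPKM.

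The 3'UTR was the most frequent label of the listed peaks. A gene can carry this label at distant places. ATM had 3'UTR peaks starting at 108231557 and 108367893 on chromosome 11, on either side of an intronic peak starting at 108242331. The shares therefore count the authors' labels and do not place peaks at the 3' end of genes. The 3'UTR held 4058 of 9466 listed peaks, or 42.9% (41.9 to 43.9), followed by stop codons with 14.5% (13.8 to 15.2) and other exonic sites with 13.7% (13.0 to 14.4). Exons of noncoding RNAs held 10.7%, introns 7.38%, start codons 5.45% and 5'UTRs 5.17%. Regions differed in how often a peak passed 2-fold. That share was 12.2% (10.5 to 14.02) at stop codons and 85.7% (82.9 to 88.2) in introns, with 39.5% in 3'UTRs and 67.7% in 5'UTRs. Median log2 fold changes ran from -0.26 at exonic sites and -0.29 at stop codons to -0.42 in 3'UTRs, -0.81 in 5'UTRs and -0.98 in introns. Relative to the median of all peaks, exonic and stop codon peaks were therefore above it and the other regions below it. Only 17.3% (15.3 to 19.4) of stop codon peaks had a value above 0, against 39.5% (36.8 to 42.2) of exonic peaks. Centring turned that order around, with 66.0% of stop codon and 60.7% of exonic peaks above the median. Expression went with the size of the values: of 10 equal groups of peaks by mean FPKM, the lowest had 80.4% of its peaks at 2-fold or more and the highest 9.64%, with median log2 fold changes of -1.20 and -0.18. Differential peaks were thus weighted towards low transcripts. Every listed peak has a p-value below 0.05, so a peak with few reads can be listed only at a large fold change. These 2-fold shares by region and by expression may therefore follow read coverage, which was not analysed here.

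**Figure D2:**
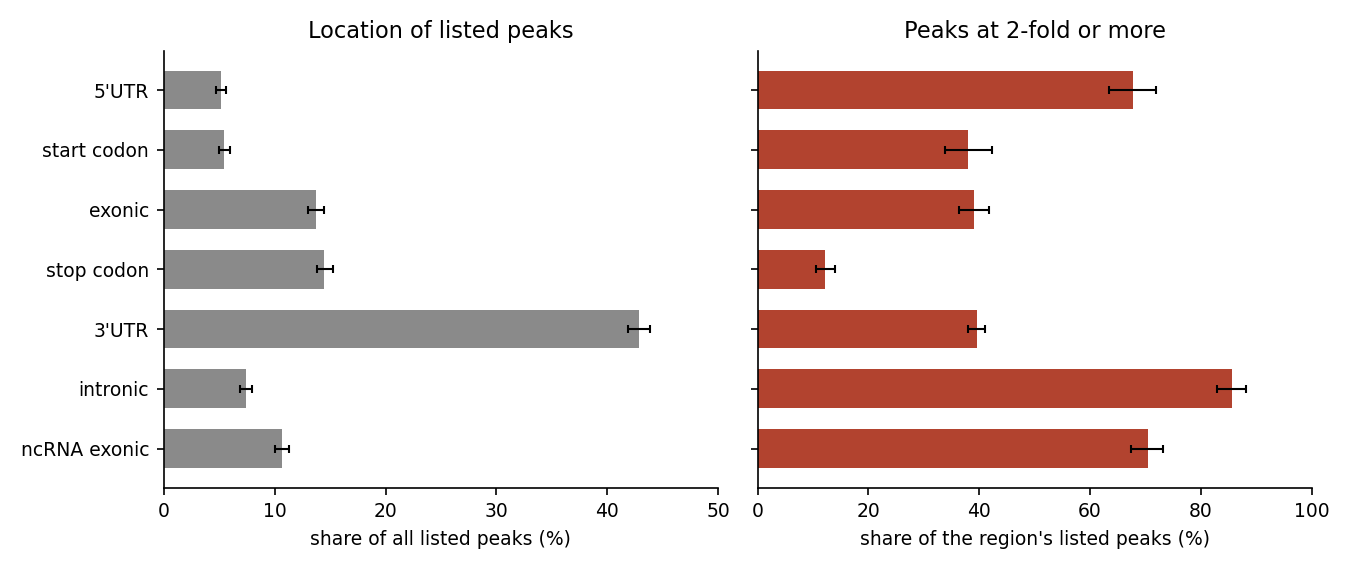
Annotated location of the 9466 listed peaks (left, share of all listed peaks in percent) and share of each region's peaks at 2-fold or more (right, in percent). Bars are shares and error bars are exact 95% intervals over peaks: the 3'UTR holds 42.9% of peaks, and the share at 2-fold or more runs from 12.2% at stop codons to 85.7% in introns.

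Input transcript levels were close between the arms. Of 5467 genes at an FPKM of at least 1 in either input, 8 were at least 2-fold higher and 8 at least 2-fold lower in the overexpression arm on the log2(FPKM + 1) scale, and 99.0% lay within 1.5-fold. With a pseudocount of 0.1 these counts were 19 and 18. The ribosome biogenesis gene WDR74 had 51.2 FPKM in the overexpression arm and 7.12 in the control arm, a log2 change of 2.69. FBXL14 had 1.84 and 0.50 FPKM, the ciliary gene BBS1 had 1.76 and 0.60, and the mitochondrial protease gene PARL had 8.17 and 4.34. Other high entries were readthrough genes or pseudogenes, whose reads can be assigned to a neighbour or to the parent gene. HNRNPUL2-BSCL2 had 4.42 FPKM and was listed at 0 in the control arm, AGAP12P had 1.16 and 0.04, MEMO1P1 had 3.87 and 1.67, PKD1P6-NPIPP1 had 4.98 and 2.33, SLC4A1APP1 had 1.13 and 0.21, and EIF1AXP1 had 14.7 and 8.19. The authors' deposited table called 17 genes differential in expression, 11 higher and 6 lower, and 1 of them passed a q-value of 0.05. That gene, ENSG00000285976, was named after its values were seen and had 48.0 and 3.03 FPKM. Its peak (chromosome 6, 63532339 to 63572679) ends next to that of PTP4A1 (63572704 to 63573299) on the same chromosome.

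Lower in the overexpression input was SNRPG, which encodes a core protein of the spliceosome, with 7.59 against 23.9 FPKM. PTP4A1, a phosphatase gene, had 26.6 against 58.8 FPKM. The adjoining ENSG00000285976, on the same strand, went the other way with 48.0 against 3.03 FPKM. Reads may have been assigned to either of them, which was not tested. CXCL8, the gene of the neutrophil chemokine interleukin 8, had 80.2 against 164.8 FPKM, a log2 change of -1.03, and the complement gene C3 had 9.15 against 17.1. The telomere gene TEN1 had 0.31 against 1.74 FPKM and the mitochondrial RNA methyltransferase gene MRM2 had 1.32 against 3.31. SENP3-EIF4A1, a readthrough gene, had 2.15 against 13.1 FPKM. TMEFF1 had 1.33 in the control arm and was listed at 0 in the overexpression arm, and FAM229A had 0.21 against 2.65. Expression p-values of the authors' deposited table were 0.13 for CXCL8, 0.017 for SNRPG and 3.81e-05 for WDR74, with q-values of 1, 1 and 0.11.

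**Figure D3:**
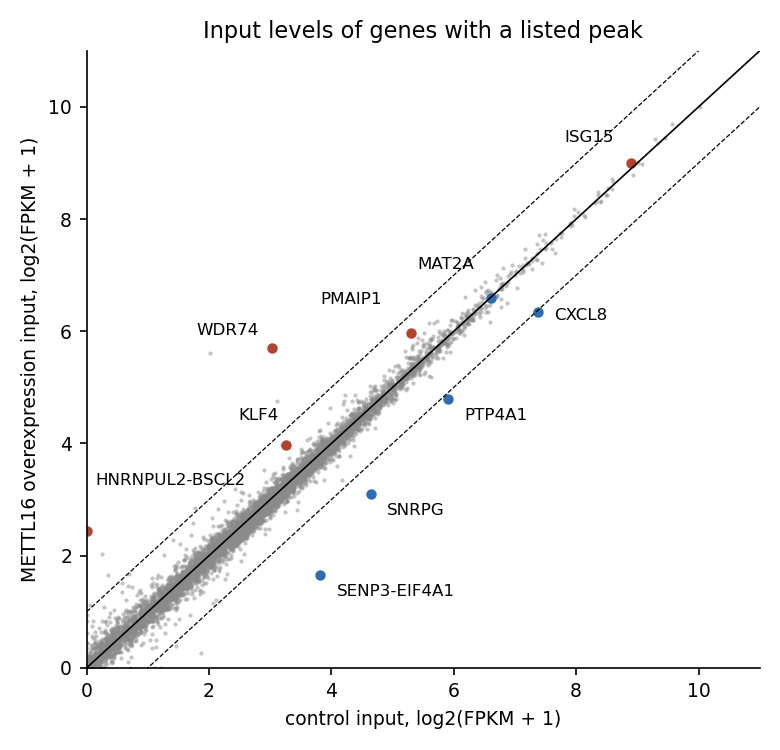
Input levels of 6546 genes in the control arm (horizontal) and the METTL16 overexpression arm (vertical), both as log2(FPKM + 1). Each point is a gene and dashed lines mark 2-fold on that scale: WDR74 (51.2 against 7.12 FPKM) lies above and SNRPG (7.59 against 23.9 FPKM) lies below the lines, while MAT2A (95.1 against 96.8 FPKM) lies on the diagonal.

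Few genes differed in both measures. Among 2388 genes with a differential peak and an FPKM of at least 1 in either input, only HNRNPUL2-BSCL2 was higher in both and only PTP4A1 was lower in both at 2-fold. The PTP4A1 peak lay in its 5'UTR with a log2 fold change of -1.63 in the authors' deposited table. Its lower input may reflect reads assigned to the adjoining ENSG00000285976, which was not tested. SNRPG was the only gene with higher m6A and a lower input level. Its peak at the stop codon (chromosome 2, 70281361 to 70292782) had a log2 fold change of 1.60 with p = 1.65e-42 in the authors' deposited table. Lower m6A with a higher input level was found for 4 genes, ENSG00000285976 among them, of which only AGAP12P had a symbol. Across the 2388 genes, the m6A and input log2 changes had a Spearman correlation of -0.09, and genes are not independent replicates. If the m6A value is relative to input, a lower input alone raises it, so the measures need not be separate. The SNRPG values, 1.60 for m6A and -1.54 for input, were of similar size and opposite sign.

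Of the gene lists, 27 had at least 3 members with a level. Their medians gave 54 percentiles, of which 9 for input and 1 for m6A lay outside the range of random lists, against 2.7 by chance. Lists share some genes, so these are not independent. Members of a list can also move together, which random lists do not reproduce, so the 2.7 applies to unrelated genes only. Counts of higher and lower members cover all genes with a level, while medians and percentiles cover those at an FPKM of at least 1 in either input. The percentiles describe these libraries and are no test of the conditions. Several differential peaks named below for list members have no adjusted p. They include those of LRPPRC, SF3B2, ITGB4, DHODH, KDM3A, GSK3B, NSD1, MX1 and the 5'UTR peak of BRCA1.

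Immediate-early, p53 target and interferon response transcripts had higher input levels in the overexpression arm. Of 15 immediate-early and MAPK feedback genes in the table, 14 were higher, with a median log2 change of 0.23, above all random lists (percentile 100). Among them KLF4, a transcription factor, had 14.8 against 8.62 FPKM, JUNB 7.41 against 5.26, IER2 12.3 against 8.91 and DUSP1, a MAPK phosphatase, 38.7 against 29.6. Of 24 p53 target and apoptosis genes, 20 were higher (median 0.14, percentile 100). PMAIP1, the BH3-only protein NOXA, had 61.4 against 38.2 FPKM, BTG2 15.8 against 11.2, GADD45A 31.7 against 23.8 and ZMAT3 4.76 against 3.44. Of 30 interferon response genes, 26 were higher (median 0.10, percentile 99.98). OASL had 52.8 against 39.3 FPKM, the immunoproteasome gene PSMB9 26.3 against 20.4, IFIT3 209.2 against 167.2 and HERC5 34.2 against 27.9. None of these named genes reached 2-fold.

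Inflammatory transcripts had lower input levels in the overexpression arm. Of 16 NF-kB and cytokine genes, 11 were lower, with a median of -0.21 (percentile 0). Besides CXCL8, the monocyte chemokine gene CCL2 had 5.997 against 9.80 FPKM, the cytokine gene LIF 18.3 against 25.3 and TNFAIP2 4.59 against 6.54. TNFAIP3, an NF-kB feedback inhibitor chosen after its values were seen, went the other way with 41.0 against 33.1 FPKM. DNA damage repair genes had a median of -0.11 (percentile 0.46), and 17 of 21 were lower. MSH6 had 5.93 against 7.43 FPKM, BRCA1 4.95 against 6.03, RPA1 12.3 against 14.5 and PARP1 5.93 against 7.00. All 4 histone genes in the table were lower (median -0.25, percentile 0.03), among them H2BC12 with 108.7 against 129.4 FPKM. Of 18 collagen and matrix genes 15 were lower (median -0.09, percentile 1.27), COL7A1 with 3.52 against 4.44 FPKM and COL6A1 with 20.1 against 23.3. Methionine, SAM and polyamine genes had a median of -0.12 over 8 genes (percentile 1.85), and 8 of 9 were lower, MTR with 4.09 against 5.12 FPKM and SHMT2 with 26.2 against 30.2. Of 25 glycolysis and hypoxia genes 19 were lower (median -0.06, percentile 2.295), CA12 with 0.65 against 1.29 FPKM, VEGFA with 10.9 against 13.9 and ENO2 with 20.96 against 25.2. The methionine, matrix and glycolysis lists returned to the range of random lists when these were not matched on expression, and the glycolysis list also did so at a pseudocount of 0.1.

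For m6A, the list of translation initiation and elongation factors stood apart. Its 19 genes had a median log2 fold change of 0.58, which was 0.95 above the median of all genes (percentile 99.995), with the peak of smallest p standing for each gene. Over all 29 listed peaks the median was smaller, at 0.23. In the authors' deposited table, EEF1A1 had 0.66, EEF2 had 0.58 at an exonic peak, and EIF3D, EIF3C and PABPC1 had differential peaks at 1.08, 4.46 and 6.11. Lower differential peaks of EIF3I and EIF3M, at -3.26 and -2.63, and a stop codon peak of EEF2 at -0.15 stood against these in the authors' deposited table. The PABPC1 peak lay in an intron, and the peaks of PABPC1, EIF3I and EIF3M had no adjusted p. EEF2 and EIF3D were chosen after their values were seen. EIF3C has a near-identical copy in the genome and EEF1A1 has many pseudogenes, so their reads can be assigned elsewhere. Input levels of these 19 genes were close between the arms (median -0.02, percentile 34.62). Of these listed peaks, 16 were higher, 13 lower and 6 differential. Among 20 listed peaks of ribosomal protein genes 10 were higher and 10 lower, with RPL3 at 1.01 and RPS2 at -1.42 in the authors' deposited table (median -0.13 with 1 peak per gene, percentile 88.12, and 0.002 over all listed peaks). The 5 listed peaks of mitochondrially encoded transcripts included 3 higher ones, and none was differential (median 0.21, percentile 90.22).

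**Figure D4:**
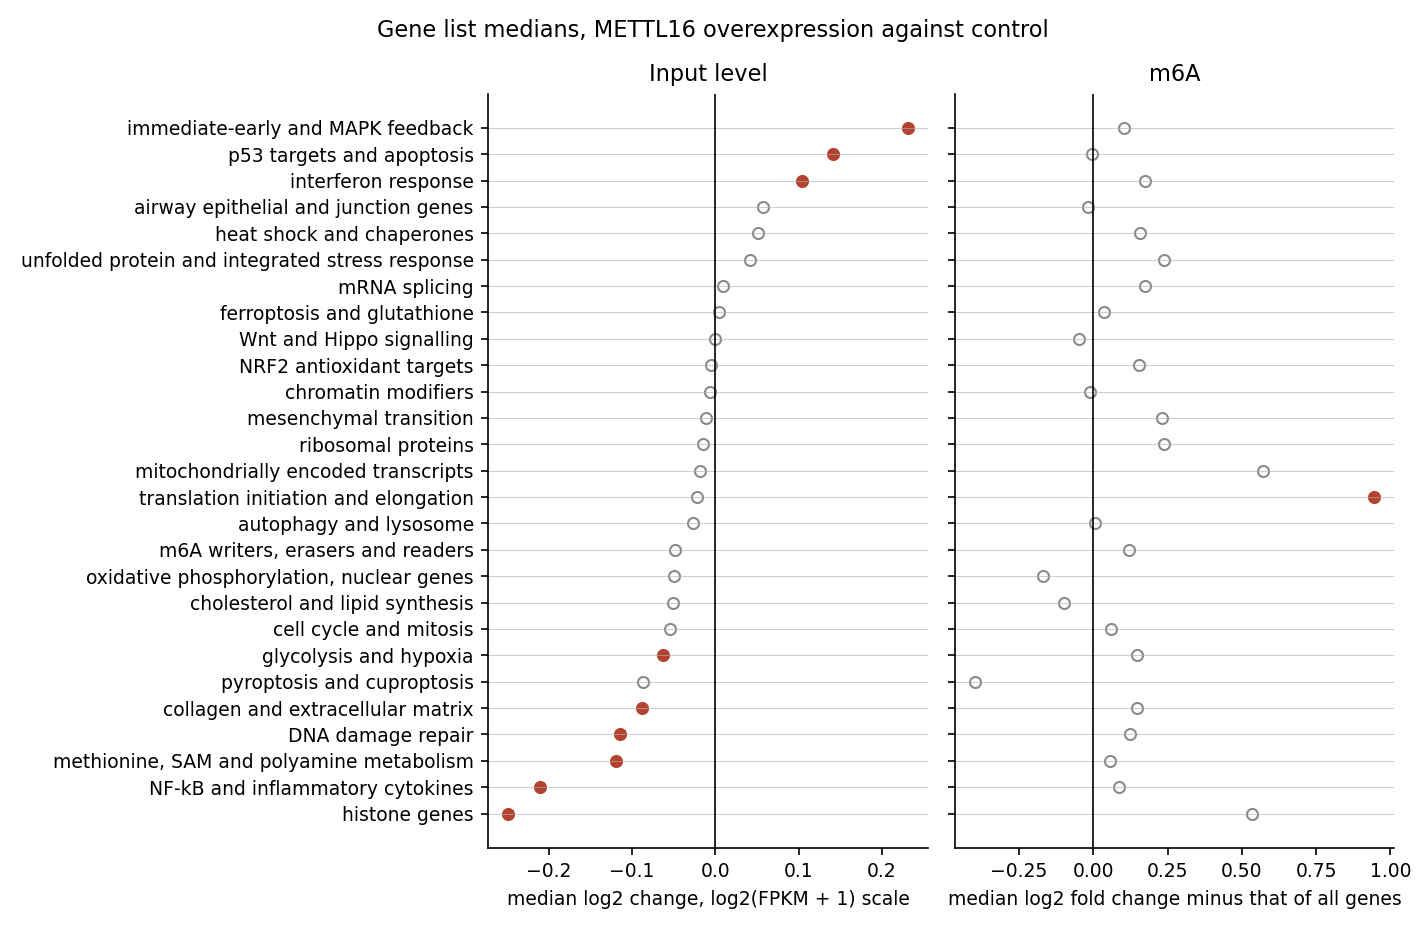
Median log2 change of 27 gene lists in input level (left, log2(FPKM + 1) scale) and in m6A (right, log2 fold change minus the median of all genes), overexpression over control. Each point is a list and filled points lie outside the range of random lists: immediate-early genes (0.23) and histone genes (-0.25) mark the ends on the left, and translation factors (0.95 above all genes) lie farthest out on the right.

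The m6A machinery was near equal in the inputs. Of 14 m6A writer, eraser and reader genes in the table, 10 were lower and 4 higher (median -0.05, percentile 21.24). METTL3, the catalytic subunit of the main m6A writer, which was named after its values were seen, had 5.53 against 5.57 FPKM, the demethylase genes ALKBH5 and FTO had 27.0 against 30.9 and 2.22 against 2.55, and RBMX had 24.0 against 26.7. Their differential peaks numbered 3 higher and 5 lower, among them LRPPRC at -4.44, FTO at 2.27, HNRNPA2B1 at -2.09 and IGF2BP3 at -1.71 in the authors' deposited table. Only the 5'UTR peak of METTL3, at -1.28, had an adjusted p below 0.05 in the authors' deposited table, and a start codon peak of METTL3 stood at -1.16. Of 22 splicing genes, 11 were higher and 11 lower in the input (median 0.01, percentile 78.3). SNRPD1 had 6.75 against 8.28 FPKM, and differential peaks of the authors' deposited table included SF3B2 at -3.74, HNRNPH1 at 2.22 and TRA2B at 1.63, 1.01 and -1.02. In methionine metabolism, MTHFD1 had an intronic peak at -2.77, MTR a 5'UTR peak at 1.95 and AHCY an intronic peak at 1.36 in the authors' deposited table.

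Epithelial and mesenchymal genes did not stand apart from random lists. The 8 airway epithelial and junction genes split into 4 higher and 4 lower in the input (median 0.06 over 7 of them, percentile 89.33), with KRT8 at 54.2 against 46.1 FPKM, OCLN at 3.89 against 3.33 and DSP at 20.4 against 18.2. The integrin gene ITGB4 had an exonic peak at 4.78 and CXADR a 3'UTR peak at -2.10 in the authors' deposited table. The 16 mesenchymal genes split into 8 and 8 (median -0.01, percentile 48.54). SMAD7 had 5.13 against 3.91 FPKM, TAGLN 9.79 against 8.16 and TNC 60.3 against 70.6, while ZEB2 had an intronic peak at 2.70 and TGFBR2 one at -1.81 in the authors' deposited table. In the matrix list, COL4A2 had a 3'UTR peak at 2.16 and COL6A1 an exonic peak at 2.001 in the authors' deposited table.

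Stress and redox lists also lay within the range of random lists in the input. The unfolded protein and integrated stress genes had 11 of 17 members higher (median 0.04, percentile 94.005), among them PPP1R15A with 70.3 against 49.9 FPKM and the chaperone gene HSPA5 with 105.8 against 79.99, and ASNS lower with 9.55 against 12.005. Heat shock genes had 7 of 9 members higher (median 0.05, percentile 90.675), with HSPA1A at 71.9 against 52.0 FPKM, although HSPA1A and HSPA1B are near-identical copies. Ferroptosis and glutathione genes split into 9 higher and 7 lower (median 0.00 over 15 of them, percentile 72.32). All 8 of their differential peaks were lower, with GCLC, the glutathione synthesis gene, at -4.35, DHODH at -3.56 and CISD1 at -3.50 in the authors' deposited table, but their m6A median of -0.33 lay within the range of random lists (percentile 35.88). NRF2 target genes had 4 higher and 6 lower members (median -0.01, percentile 61.2), with SLC7A11, the cystine transporter gene, at 3.32 against 2.78 FPKM and NFE2L2 at 1.43 by an intronic m6A peak in the authors' deposited table.

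Cell cycle genes were mostly lower in the input, 18 of 22, within the range of random lists (median -0.05, percentile 3.55). E2F1 had 12.6 against 16.5 FPKM, CDK1 9.07 against 11.5, E2F2 1.07 against 1.53 and TOP2A 26.4 against 31.9. Of its 5 differential peaks 4 were lower, E2F2 at -2.22, CDK2 at -1.20, RB1 at -1.19 and RRM2 at -1.05 in the authors' deposited table. In the repair list 7 differential peaks were higher and 12 lower. There, the authors' deposited table gave BRCA1 a 5'UTR peak at 3.64 and a 3'UTR peak at -1.56, FANCA 3'UTR peaks at 3.29 and -1.11, and MRE11 a 3'UTR peak at -3.57. Among p53 targets, BCL2 had -2.10 and SESN1 1.75 in the authors' deposited table. In the glycolysis list, KDM3A had an intronic peak at -5.71, GPI an intronic peak at -3.68 and PDK1 a 3'UTR peak at -3.09 in the authors' deposited table.

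Metabolic and degradation lists gave these values. Nuclear oxidative phosphorylation genes had 10 of 13 members lower in the input (median -0.05, percentile 24.77), with SDHC at 17.3 against 20.04 FPKM, and peaks of NDUFA10 at 3.26, NDUFS3 at -2.67, COX7A2 at -2.56 and UQCRC2 at -2.36 in the authors' deposited table. Mitochondrially encoded transcripts had 3 of 5 members lower (median -0.02, percentile 36.84), with MT-CO2 at 437.5 against 484.6 FPKM. Cholesterol and lipid genes had 9 of 13 members lower (median -0.05, percentile 20.8), and all 4 of their differential peaks were lower, ELOVL6 at -2.54, MVD at -2.33 and DHCR7 at -1.97 in the authors' deposited table. Autophagy and lysosome genes had 16 of 24 members lower (median -0.03 over 23 genes, percentile 43.2), with 5 higher and 5 lower differential peaks, CTSB at -4.92, ATG2B at -4.02 and LAMP1 at 2.81 in the authors' deposited table. Pyroptosis and cuproptosis genes had 12 of 16 members lower (median -0.09 over 12 genes, percentile 7.5), with DLD at 10.2 against 11.9 FPKM and ATP7B at -3.49 by m6A in the authors' deposited table. Ribosomal protein genes had 12 of 18 members lower (median -0.02, percentile 35.52), with RPS3 at 80.6 against 91.0 FPKM.

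In signalling and chromatin lists, Wnt and Hippo genes had 8 higher and 9 lower members in the input (median -0.001, percentile 71.42), with WNT5A at 5.16 against 6.17 FPKM. Of their 25 listed m6A peaks 23 were lower, with GSK3B at -4.57, DVL3 at -3.71 and LRP6 at -3.48, -1.24 and 1.29 in the authors' deposited table, and their m6A median of -0.41 was at percentile 18.73. Chromatin modifier genes had 13 higher and 17 lower members (median -0.01 over 29 genes, percentile 74.41) and 73 listed peaks, with NSD1 at -5.20, NSD3 at -3.56 and ARID1A at 2.78 in the authors' deposited table. All 16 listed peaks of the immediate-early list were lower, SPRED1 at -1.21 and DUSP6 at -1.10 in the authors' deposited table, but their m6A median of -0.26 was above that of all genes (percentile 47.62). The DUSP6 peak overlapped a peak of ENSG00000274021 on the opposite strand, a gene chosen after its values were seen. Of the 57 listed interferon response peaks 46 were lower (median -0.19, percentile 64.96), with MX1 at -3.25 and CXCL10 at -1.21 in the authors' deposited table. In the NF-kB list, the authors' deposited table gave IL32 a value of -2.25, BIRC3 one of -2.23 and SOD2 values of 2.10 in an intron and -1.06 in the 5'UTR.

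Markers of other cell types were few. From the fibroblast and smooth muscle list 2 of 13 genes were in the table, THY1 with 25.7 against 24.7 FPKM and PDGFRB with 1.55 against 1.51. From the leukocyte list 2 of 18 were, CD68 with 57.7 against 41.6 FPKM and CSF1R with 0.03 against 0.08. From the endothelial list, 0 of 10 genes were in the table. The table holds only genes with a listed peak, so a marker outside it has no value here.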

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

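The removal of peaks shared between strands or between duplicated copies was chosen after seeing the data, and the other alternatives were planned. Cause was not tested except where a stricter limit or filter leaves fewer peaks or genes by construction. Of the counts of differential peaks (1558 higher, 2574 lower), counting overlapping peaks once, 1 peak per gene, an FPKM of at least 1 in both inputs and a 1.5-fold threshold stayed within 1.5 times, as did the removal of 268 shared peaks (1522 and 2505). Stricter limits gave 601 and 1053 at p below 0.01, 267 and 475 at adjusted p below 0.05, 743 and 1205 at 4-fold, and 455 and 720 at an FPKM of at least 5 in both inputs, and with no fold threshold there were 2696 and 6770. The lower share of 62.3% was 64.0% at adjusted p below 0.05 and 71.5% with no fold threshold. It reversed to 49.2% when log2 fold changes were centred on their median, which removes the common shift by construction. The median of -0.38 was -0.35 and -0.29 at an FPKM of at least 1 and 5 in both inputs, and -0.40 with 1 peak per gene. With 1 peak per gene, 3'UTR, stop codon and exonic shares were 41.4%, 16.9% and 12.6%, and at p below 0.01 the stop codon and exonic shares were 17.2% and 15.3%.

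Genes 2-fold apart in the inputs (8 higher, 8 lower) numbered 19 and 18 at a pseudocount of 0.1, 19 and 19 at 0.01, 3 and 3 at 5, 4 and 4 at an FPKM of at least 5 in either input, 4 and 4 at an FPKM of at least 1 in both, 30 and 22 at 1.5-fold, 3 and 1 at 4-fold, and 19 and 19 by the authors' fold change. Centring, rescaling, no filter and the authors' call kept these counts within 1.5 times. The Spearman correlation of -0.09 between m6A and input was -0.046 at an FPKM of at least 5 in both inputs. At 1.5-fold the classes held 2 genes higher in both, 4 with higher m6A and lower input, 13 with lower m6A and higher input, and 6 lower in both. At 4-fold the last 3 classes held 0, 1 and 0 genes. At an FPKM of at least 5 in both inputs, the class higher in both held 0 genes and that with lower m6A and higher input 1. Of 135 list percentiles under alternatives, 129 stayed on their side of the limits, 4 returned to the range (methionine at 2.68, matrix at 2.89 and glycolysis at 8.54 without matching on expression, and glycolysis at 2.93 at a pseudocount of 0.1) and 2 left it, the m6A percentiles of interferon response (98.66) and unfolded protein genes (97.655) without matching on expression. Alternatives for METTL16 expression and for the fold enrichment of peaks were not run, since neither value was analysed here. No paired analysis was possible because each group held 1 library.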

Other observations

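The tests on duplicated families, on low expression and on weaker enrichment were chosen after their patterns were seen and revised after first values were seen, the test on scaling was chosen after the pattern was seen, and those on opposite strands were set before their values were seen. Genes named in this part were chosen after their values were seen, and no effect of METTL16 itself was tested, since each arm had 1 library per kind.

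Interferon-stimulated genes were among the abundant transcripts of both arms. ISG15, a ubiquitin-like antiviral protein gene, had 511.3 FPKM in the overexpression input and 474.4 in the control input, IFI6 had 342.7 and 363.4, IFIT1 213.0 and 179.5, and IFITM3 266.7 and 279.0. The antigen presentation gene B2M had 656.4 and 646.2 FPKM. The median level of listed interferon genes was 53.1 FPKM, against medians of 4.97 and 5.03 over all genes of the table. A library without transfection was not analysed here. RNF213, an interferon-induced ubiquitin ligase gene, had 11 listed peaks, the most of any gene, and its exonic and stop codon peaks lay between -0.09 and -0.44, against 2.17 and 0.79 for its intronic peaks, in the authors' deposited table. The long noncoding RNA MALAT1, with 683.9 and 623.5 FPKM, had peaks at -0.08 and -0.13 in the authors' deposited table.

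GNAS had unlike m6A values at its peak labelled 5'UTR and among its peaks labelled 3'UTR. Whether the latter all lie in the 3'UTR of its main transcript was not checked. The peak labelled 5'UTR (chromosome 20, 58892344 to 58893507) had a log2 fold change of -1.33 in the authors' deposited table. Those labelled 3'UTR at 58905221 to 58905671 and 58908621 to 58909571 had 1.52 and 1.51, while the one farthest downstream (58910921 to 58911192) had 0.12. The input of GNAS was 23.8 against 23.3 FPKM. The small nuclear RNA 7SK had a peak with p = 1.27e-138 and a log2 fold change of -0.31 in the authors' deposited table, while its input was listed at 0.04 and 0.02 FPKM.

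Peaks on opposite strands at the same place had nearly equal values. Of 72 pairs that overlapped by at least 50% of both peaks, MAT2A with GGCX had been seen beforehand, and 70 of the other 71 shared their sign (98.6%, 92.4 to 99.96), with GATC and SRSF9 as the exception. Nearby opposite-strand peaks without overlap shared it in 646 of 995 pairs (64.9%, 61.9 to 67.9), and their median absolute difference was 15.1 times that of the overlapping pairs (1.23 against 0.08), which argues against genes of one neighbourhood moving together. Reads assigned to genes on both strands are consistent with the 98.6%, as are pairs such as GAPDH with ENSG00000269968, at mean levels of 1029 and 0.02 FPKM. The GGCX value of 0.74 may therefore come from MAT2A transcripts, a hypothesis that reads with strand could test.

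Of the 20 genes named for the largest m6A values, 8 belonged to duplicated families, SMG1P5 and STAG3L1 among them, and others such as MLH3 and SNX19 did not. Over all 40 listed families, 18 of 79 differential peaks with a level reached 16-fold (22.8%, 14.1 to 33.6) against 6.18% of other genes at equal expression, a ratio of 3.68, but 9 families had been listed with such members already seen. Leaving these out, a step taken after the family values had been seen and so no independent test, 7 of 37 peaks reached it (18.9%, 7.96 to 35.2) against 7.27%, a ratio of 2.60, and 4 of the 23 families held copies at 4-fold in both directions. Of 10000 draws of other differential peaks matched on expression, 1.36% held as many. These draws replaced a first comparison in which the interval from 7.96 barely left out 7.27. They treat peaks of the same family as independent and match on gene FPKM, which shared reads can also change. Low expression can therefore not be excluded. Reads shared between near-identical copies are a candidate explanation of the ratio of 2.60, on few peaks.

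For the excess of lower peaks, one scaling factor for the whole immunoprecipitated library predicts equal medians of exonic and stop codon peaks at equal expression, and over 5 expression groups the difference (exonic minus stop codon) was over 0.1 in size only in the lowest group, at -0.42. Weaker enrichment in the overexpression immunoprecipitate predicts more higher values at exonic sites than at stop codons, and a first test without centring gave a difference of 8.78 to 30.3 percentage points. After centring, a requirement added once that first result had been seen, it ran from -15.9 to 7.73 and was above 0 in 2 of 5 groups. Weaker enrichment also predicts medians of abundant transcripts above that of all peaks (-0.38). Ribosomal protein (0.002), translation factor (0.23) and mitochondrially encoded transcripts (0.21) lay above it, but so did the most expressed of 10 groups of peaks (-0.18). The ribosomal and mitochondrial lists lay within random lists matched on expression (percentiles 88.12 and 90.22, with 1 peak per gene). Matching on expression takes away the predicted effect of abundance, so these percentiles cannot decide for or against weaker enrichment. Translation factors lay outside random lists matched on expression (percentile 99.995, for their median of 0.58 with 1 peak per gene). Levels still differ within a bin, and the most expressed of 10 groups of peaks spans 30.1 to 1029 FPKM. Expression level is therefore not excluded as an account of that median. Over all listed peaks, centring turned around the order of the shares only. The exonic median stayed above the stop codon median, at 0.12 against 0.10 after centring. Scaling, weaker enrichment and an effect of METTL16 itself cannot be told apart, because each arm had 1 immunoprecipitate.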
